A study of Mus musculus and Homo sapiens with 20 samples.

How the data were processed

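RNA sequencing was measured in 20 libraries from murine 4T1 and human BT549 triple-negative breast cancer cells. Per the labels' protocols, total RNA was taken from control cells and from cells edited at SOX4 or ITGAV, libraries were made with a TruSeq RNA v2 kit, which does not mark strand, and sequenced as single-end reads on a NextSeq 500. The labels give 10 groups of 2 libraries: in each cell line a LacZ guide as control, 2 guides against SOX4 (gRNA1 and gRNA2) and 2 guides against ITGAV (gRNA1 and gRNA4). The protocol speaks of biological triplicates, while 2 libraries per group are listed. The guide named gRNA4 in the titles is called gRNA-2 in the descriptions, and the titles were followed.

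The authors deposited 8 tables, each comparing the 2 libraries of an edited group with the 2 LacZ libraries of its cell line. The deposited signal is a normalised mean, baseMean, over the 4 libraries of a table, per the file headers. Deposited fold changes are on the log2 scale with their standard errors, per the file headers. The deposited score is the Wald statistic, which equals the log2 fold change divided by its standard error. The deposited p-value is that of the Wald test, and the deposited adjusted p-value is missing for genes with a low mean. DESeq2 (1.8.1 and 3.5) with default settings and Cufflinks are named in the submitters' processing notes, with the builds hg19 and mm9. The aligner, the counting tool and the annotation are not given in the sources used here. The design text also says that human and mouse homologues were matched with the Mouse Genome Informatics annotation.

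The deposited log2 fold change was LacZ over edited: with that reading the LacZ level implied by each table was proportional across the 4 tables of a cell line, with a spread of at most 0.00142 in log2 in 4T1, against at least 0.104 with the other reading. Signs were therefore turned, and every log2 value below is edited over LacZ. All 8 tables list human gene symbols and human Ensembl identifiers, the 4T1 tables included; of the 12809 genes listed for 4T1, 88.6% have a mouse gene of the same name, and those without hold 4.43% of the reads. The gene lists were therefore matched by human symbol in both cell lines, and the mouse lists planned for 4T1 were not used. In the 4T1 tables a gene name is the name given there, and the route by which mouse reads came to it is not stated.

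Counts per library were not among the columns. They were recovered from the deposited means, because each mean is a sum of whole counts divided by size factors. Whole counts were recovered for all 12809 genes in 4T1 and all 16092 in BT549, with means rebuilt to a relative tolerance of 1.5e-14. At a baseMean of 50 or more, log2 fold changes lay within 0.0715 of the deposited ones. The 2 libraries of a group carry no replicate number in this recovery and are called a and b. The self-test recovered 1999 of 2000 simulated genes of 4T1. Normalised counts per library are recovered counts divided by median-of-ratios size factors.

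The following choices were made before the data were examined. A gene was called for a guide at an adjusted p under 0.05 of the DESeq2 test that the authors deposited, and for a target when both guides passed with the same sign. Named genes were SOX4 and ITGAV; the 10 genes per direction with the largest smaller absolute log2 fold change of the 2 guides, among called genes with a baseMean of at least 50 in both tables and without predicted names; up to 4 called members of each gene list, or at most 2 with the smallest p where none was called; and the 5 genes per direction with the largest z for each difference. Differences between guides, targets and cell lines were tested as z, the difference of log2 fold changes over its standard error, with Benjamini-Hochberg adjustment. The standard error of a difference within a cell line left out the covariance that the shared LacZ libraries bring, which makes it too large, while that between cell lines included it. Cell lines were compared over the 12326 gene names listed in both, of which 11278 and 11350 had values for SOX4 and ITGAV. The 24 gene lists, fixed at the same time, were tested with limma's cameraPR on the mean deposited Wald statistic of both guides, with a preset correlation of 0.01 and adjustment over all lists and comparisons; a list needed 3 measured members.

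Unchanged groups with a shared simulated control were drawn 100 times to show what shared controls give with no effect. The noise came from the deposited standard errors, and the LacZ counts themselves did not enter. Alternatives planned with these choices were stricter and looser thresholds of 0.01 and 0.1, a minimum absolute log2 fold change of 1, adjustment over every deposited p, a baseMean of at least 50, a combined statistic of both guides, subtraction of the shared covariance, and preset correlations of 0.05 and 0.1, ranks, the log2 fold change, single guides and 10000 random lists matched on baseMean for the list tests. Added after the data were seen were a limma (voom) fit of the recovered counts, over genes with a mean of at least 10 counts per library and all 10 libraries of a cell line together; the same fit with each library left out, with no filter on low counts, and with the 2 groups of a comparison alone; camera on that fit with a preset and an estimated correlation; list tests with the edited gene left out of lists that hold it; and a test of Gene Ontology terms of 15 to 300 measured genes. The plan named edgeR for tables with counts per sample, and edgeR was not run. The DESeq2 test that the authors deposited was kept as the main one.

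Tests used simulated data. With the deposited standard errors of 4T1 SOX4, both-guide calls found 30.1%, 79.0% and 100% of genes changed by 0.5, 1 and 2 in log2 (73, 62 and 65 genes); for BT549 ITGAV the shares were 77.1%, 100% and 100% (70, 59 and 71 genes). Of unchanged genes, 0 of 6463 (4T1) and 1 of 9233 (BT549) passed. In another 4T1 SOX4 simulation, limma found 21.1%, 86.4% and 98.4% at each size (71, 66 and 63 genes). CameraPR called 8 of 10 shifted and 0 of 90 unshifted lists of neither comparison. Neither test is shown to match real noise or correlation.

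Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.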

Results

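Transcripts were measured by RNA sequencing in 2 triple-negative breast cancer cell lines, murine 4T1 and human BT549, edited with guide RNAs against SOX4, a transcription factor, or against ITGAV. The latter encodes the integrin alpha-V chain, which binds extracellular matrix and helps to release TGF-beta from its latent form. Each of the 10 groups had 2 libraries: in each cell line a LacZ control, SOX4 gRNA1 and gRNA2, and ITGAV gRNA1 and gRNA4. Recovered totals ran from 3153476 to 8861738 counts per library in 4T1, with reads in 11076 to 11613 genes. In BT549 they ran from 12110549 to 33271301 counts, with reads in 13992 to 14728 genes. Between the 2 libraries of a group the mean chi-square per gene was 1.16 to 1.32 in 4T1 and 1.29 to 2.60 in BT549, where 1 is sampling noise. The labels speak of biological triplicates, yet each group has 2 libraries, and how these relate to the cultures is not stated. SDs therefore measure only the spread between these samples, which may be technical, and p-values are not shown to cover that between cultures. The deposited DESeq2 errors imply a larger dispersion (relative variance beyond sampling noise) than these libraries show. At a baseMean of 50 to 500 it was 0.0144 against 0.00114 for 4T1 SOX4 gRNA1, and 0.0108 against 0.00144 for BT549 ITGAV gRNA4. From 5000 up the values were closer, 0.000646 against 0.000507 and 0.00104 against 0.000979. The descriptions call ITGAV gRNA4 gRNA-2, and the titles are followed. Genes with near-identical copies, such as HLA, histone, tubulin and keratin genes, have uncertain counts because the counting method is not stated.

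The edited genes came first, as a check of the labels. In 4T1, the SOX4 normalised count (gene ENSG00000124766) was 1640 ± 45.9 (SD, n = 2) with LacZ, 1068 ± 20.3 (SD, n = 2) with SOX4 gRNA1 and 1134 ± 55.6 (SD, n = 2) with SOX4 gRNA2. The log2 fold changes of SOX4 were -0.62 ± 0.08 (SE) and -0.55 ± 0.08 (SE), with DESeq2 adjusted p = 2.18e-11 and 4.16e-10 in the authors' deposited tables. The ITGAV count in 4T1 (gene ENSG00000138448) was 917.9 ± 32.0 (SD, n = 2) with LacZ, 343 ± 12.4 (SD, n = 2) with ITGAV gRNA1 and 359 ± 2.39 (SD, n = 2) with ITGAV gRNA4. Log2 fold changes of ITGAV were -1.42 ± 0.11 (SE) and -1.35 ± 0.10 (SE), with DESeq2 adjusted p = 3.74e-36 and 3.90e-41 in the authors' deposited tables. In BT549, ITGAV was 4623 ± 359 (SD, n = 2) with LacZ, 3721 ± 26.8 (SD, n = 2) with ITGAV gRNA1 and 2270 ± 212 (SD, n = 2) with ITGAV gRNA4. By the authors' deposited tables, ITGAV there fell by 0.31 ± 0.06 (SE) and 1.03 ± 0.08 (SE) on the log2 scale, with DESeq2 adjusted p = 7.76e-06 and 5.29e-38. SOX4 in BT549 was 2024 ± 74.7 (SD, n = 2) with LacZ, 1729 ± 79.3 (SD, n = 2) with SOX4 gRNA1 and 1936 ± 71.3 (SD, n = 2) with SOX4 gRNA2. Its log2 fold changes of -0.23 ± 0.08 (SE) and -0.06 ± 0.07 (SE) did not pass DESeq2 in the authors' deposited tables, with adjusted p = 0.0904 and 0.668. SOX4 transcript therefore gives no check of the labels in BT549, where a small edit can leave its level as it was. Limma gave an adjusted p = 0.00560 for gRNA1.

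**Figure D1:**
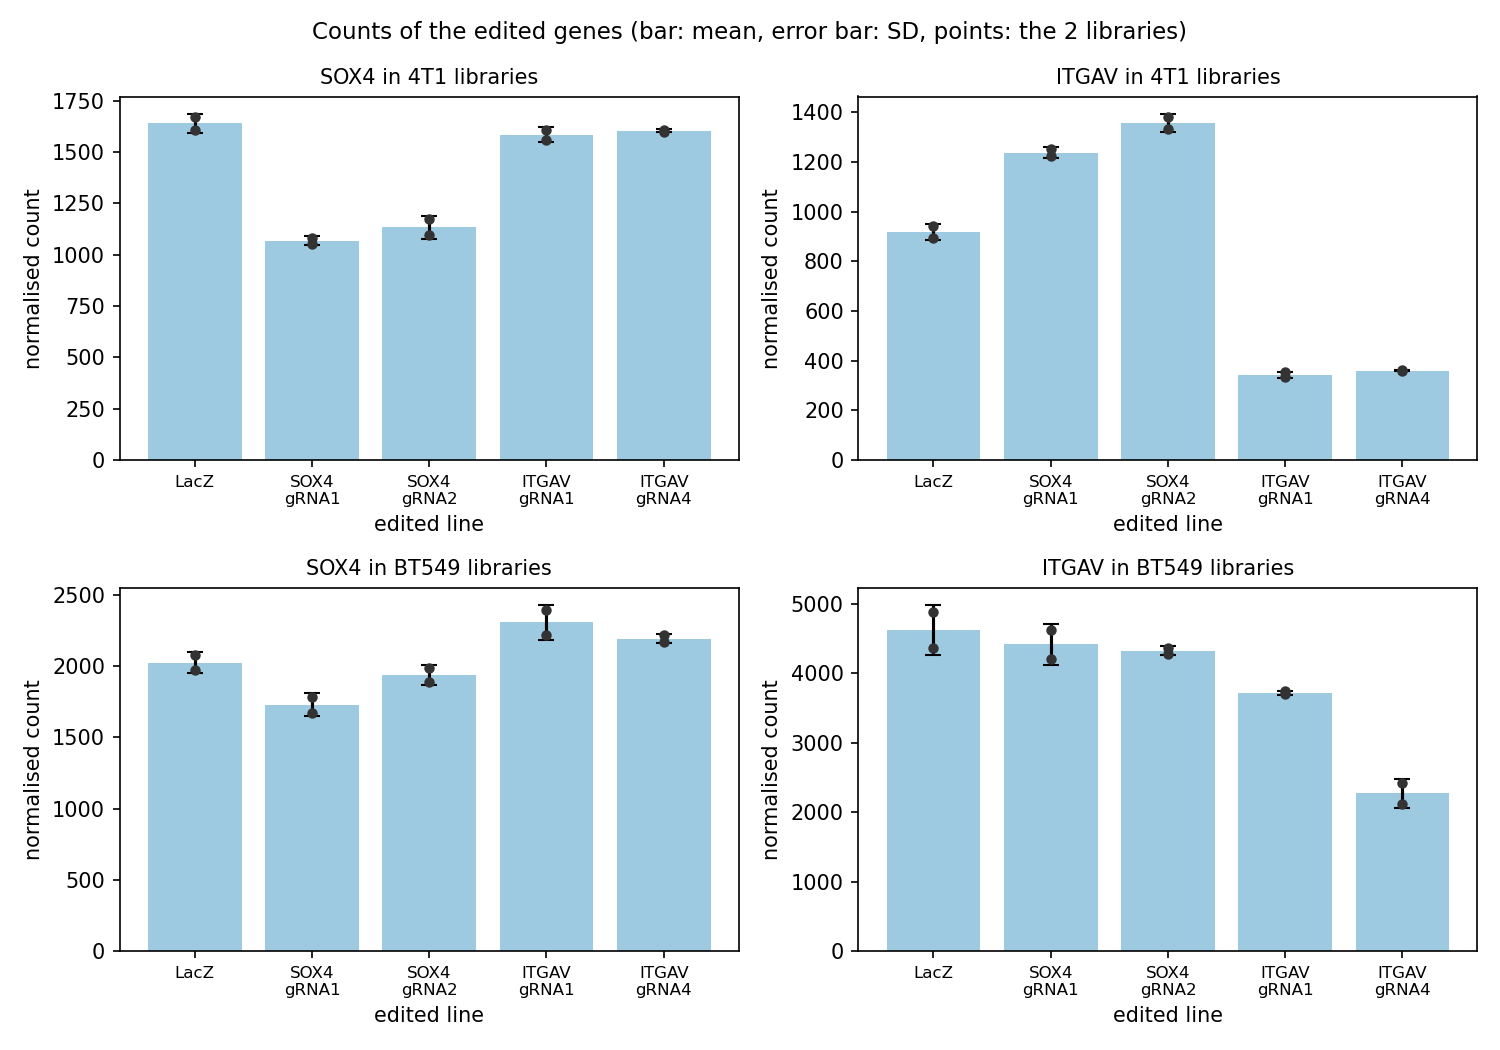
Normalised counts of SOX4 and ITGAV in the 5 groups of each cell line, with bars for the mean, error bars for the SD and points for the 2 libraries. ITGAV ranged from 334.7 to 360.7 in the 4T1 libraries with ITGAV guides, below the 895 and 940.5 of the LacZ libraries.

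SOX4 guides in 4T1 raised the lists of cholesterol synthesis, MHC class I presentation and integrins. The 2 guides called 756 and 767 genes, and 527 passed with both in the same direction, 284 higher and 243 lower, with 0 in opposite directions. Independent lists of these sizes would share 42.4 genes in the same direction, and simulated unchanged groups with a shared control shared at most 1. Such values near 0 follow from the adjustment, which leaves few calls in unchanged groups. Here and below they do not gauge what shared controls add among changed genes. Part of the excess, here and for the other pairs of guides, may come from the shared LacZ libraries, which cannot be split with 2 of them. ABCC3, an exporter of bile salts and drug conjugates, rose by 2.77 ± 0.37 (SE) and 2.26 ± 0.38 (SE) in log2 in the authors' deposited tables. CP, the copper-binding ferroxidase ceruloplasmin, rose by 1.80 and 1.66 and SPP1, the secreted matrix protein osteopontin, by 1.94 and 1.66 in the authors' deposited tables. XDH, an enzyme of purine breakdown, rose by 2.56 and 1.94 in the authors' deposited tables. LGR6, a receptor for R-spondins, TGM2, a protein cross-linking enzyme, GPR39, a zinc-sensing receptor, and ENPP5 rose by 1.17 to 1.62 in the authors' deposited tables. Genes that fell were TTYH3, a chloride channel family member, at -2.29 ± 0.23 (SE) and -1.65 ± 0.19 (SE) in the authors' deposited tables, and MARCKSL1, which binds actin. MARCKSL1 was at -2.24 ± 0.13 (SE) and -1.41 ± 0.11 (SE) in the authors' deposited tables. DBN1, the actin-binding protein drebrin, PLXNB1, a semaphorin receptor, IGSF9, a neuronal adhesion protein, and MEX3A, an RNA-binding protein, lay between -1.98 and -1.22 with both guides in the authors' deposited tables. CTXN1, SULF2, a heparan sulfate sulfatase, TEAD2, a transcription factor of Hippo signalling, and ID3, an inhibitor of basic helix-loop-helix factors, fell by 1.01 to 2.63 in the authors' deposited tables.

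Among gene lists in 4T1 with SOX4 guides, cholesterol synthesis had the most called members and the lowest p, with 11 of 23 measured members higher with both guides and 0 lower, or 14 when adjusted over the list alone. Its median log2 was 0.55 (limma cameraPR adjusted p = 1.36e-23, and 0.0132 with an estimated correlation). Its members INSIG1, a sterol sensor, and LSS, which closes the sterol ring, rose by 1.03 and 1.18 and by 0.89 and 1.16 in the authors' deposited tables. MSMO1 and CYP51A1, later enzymes of the path, rose by 0.76 to 0.95 in the authors' deposited tables. MHC class I presentation rose, with 5 of 21 members higher and 0 lower, or 7 adjusted over the list alone (median 0.32, adjusted p = 6.43e-09, and 0.0201 with an estimated correlation). TAP2, a peptide transporter, rose by 1.31 ± 0.36 (SE) and 1.53 ± 0.33 (SE) in the authors' deposited tables. HLA-B, an antigen-presenting chain, rose by 0.27 and 0.41 and the folding proteins CANX and PDIA3 by 0.17 to 0.29 in the authors' deposited tables. Integrins rose, with 5 of 16 higher and 0 lower, also 5 adjusted over the list alone (median 0.28, adjusted p = 1.45e-07, and 0.0251 with an estimated correlation). ITGB2, the beta chain of leukocyte integrins, rose by 1.65 and 1.56, ITGAV itself by 0.43 and 0.55, and ITGB4 and ITGA6, chains of the laminin receptor of epithelia, by 0.38 to 0.61 in the authors' deposited tables.

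Epithelial markers in the same comparison had 3 of 27 members higher and 0 lower, or 5 adjusted over the list alone (median 0.14, adjusted p = 1.53e-05, but adjusted p = 0.0669 with an estimated correlation). KRT8, a keratin, CDH1, the adhesion protein E-cadherin, and ST14, a membrane protease, were higher by 0.28 to 0.64 in the authors' deposited tables. Extracellular matrix genes went both ways, with 5 of 33 higher and 1 lower, or 7 and 3 adjusted over the list alone (adjusted p = 0.00419 in the upward direction, and adjusted p = 0.0513 with an estimated correlation). The median of -0.000177 and the mean of -0.07 had the other sign. MMP3, a matrix protease, rose by 0.96 and 0.59, COL5A1, a collagen chain, by 0.64 and 0.53 and LAMB3, a laminin chain, by 0.37 and 0.35 in the authors' deposited tables. TNC, the matrix protein tenascin C, fell by 1.19 and 0.60 in the authors' deposited tables. Interferon receptors and checkpoint genes passed the preset test with 1 of 11 members higher, 1 adjusted over the list alone (median 0.24, adjusted p = 0.0171, but adjusted p = 0.121 with an estimated correlation). This was NT5E, an ectoenzyme that makes adenosine, at 0.70 and 0.64 in the authors' deposited tables. The lists of mesenchymal markers (adjusted p = 0.468), TGF-beta pathway (0.154), NF-kB targets (0.118), p53 targets (0.102), cell cycle genes (0.995), hypoxia and glycolysis (0.983) and stress response (0.433) did not pass cameraPR. Of mesenchymal markers, 1 of 20 was higher and 3 lower, or 1 and 4 adjusted over the list alone: S100A4, a calcium-binding protein, was higher by 0.54 and 0.20, and TNC, MYL9 and TPM1 were lower in the authors' deposited tables. Of the TGF-beta list, 3 of 29 were higher and 2 lower by either adjustment, over all genes or the list alone. LTBP3 and LTBP1, latent TGF-beta binding proteins, were higher by 0.40 to 0.73, ID1, a partner of ID3 in blocking differentiation factors, was at -0.75 and -1.28, and ID3 was lower too in the authors' deposited tables. Of hypoxia and glycolysis, 1 of 27 was higher and 3 lower, or 2 and 3 adjusted over the list alone: SLC2A1, a glucose transporter, was higher by 0.42 and 0.48, and PGK1, ENO1 and PKM, glycolytic enzymes, were lower, PGK1 at -0.28 and -0.26 in the authors' deposited tables. The stress response had 3 of 24 higher and 3 lower, or 4 and 4 adjusted over the list alone, with MANF and HSPA5, of the endoplasmic reticulum, higher by 0.23 to 0.32 and ASNS and PSAT1, enzymes of amino acid synthesis, at -0.43 to -0.24 in the authors' deposited tables. The NF-kB, p53 and cell cycle lists had 1 called member each, also 1 adjusted over the list alone. These were NFKB2, an NF-kB subunit at -0.38 and -0.27, PLK2, a kinase of the p53 response at -0.95 and -0.83, and MCM6, of DNA replication, at 0.25 and 0.20 in the authors' deposited tables.

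ITGAV guides in 4T1 lowered the lists of integrins, extracellular matrix and stress response and raised those of epithelial markers and cholesterol synthesis. The guides called 551 and 610 genes, and 401 passed with both in the same direction, 131 higher and 270 lower, against 30.5 for independent lists and 0 in simulated unchanged groups. HSP90AA1, a chaperone, was the 1 gene called in opposite directions. FOS and FOSB, subunits of the AP-1 transcription factor, fell by 3.37 ± 0.14 (SE) and 2.45 ± 0.11 (SE) and by 3.28 ± 0.19 (SE) and 2.65 ± 0.15 (SE) on the log2 scale in the authors' deposited tables. MMP9, a gelatinase, ID1, and DUSP1, a MAP kinase phosphatase, fell by 0.84 to 1.25 in the authors' deposited tables. ATP1B1, a chain of the sodium pump, CD47, a surface signal against phagocytosis, PSAP, a lysosomal activator protein, and ECM1, a matrix protein, fell by 0.74 to 1.24 in the authors' deposited tables. HIST3H2A, a histone, rose by 1.03 ± 0.10 (SE) and 1.15 ± 0.09 (SE), and SPRY1, a brake on growth factor signals, by 0.90 and 1.02 in the authors' deposited tables. RIPK4, a kinase of keratinocytes, rose by 1.09 and 0.86 in the authors' deposited tables. KRT4 and KRT75, keratins, PRPH, an intermediate filament protein, RAB25, an epithelial trafficking protein, and MYH14, a myosin, rose by 0.71 to 0.92 in the authors' deposited tables.

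Integrins as a list fell with ITGAV guides in 4T1, with 6 of 17 members lower and 0 higher, or 7 adjusted over the list alone (median -0.35, limma cameraPR adjusted p = 3.79e-13, and 0.0195 with an estimated correlation). The list holds the edited gene: without ITGAV, 5 of 16 were lower and 0 higher (median -0.35, limma cameraPR adjusted p = 7.33e-08, and 0.0231 with an estimated correlation). ITGA2, ITGA5 and ITGB1, receptor chains for collagen and fibronectin, lay between -0.88 and -0.39 in the authors' deposited tables. Extracellular matrix genes fell, with 8 of 35 lower and 1 higher by either adjustment, over all genes or adjusted over the list alone (median -0.18, adjusted p = 1.05e-07, and 0.0195 with an estimated correlation). SPARC, a collagen-binding protein, fell by 0.68 and 0.78, MMP14, a membrane protease, by 0.47 and 0.51, and MMP3 by 1.92 and 0.59 in the authors' deposited tables. Mesenchymal markers fell, with 4 of 21 lower and 0 higher, also 4 adjusted over the list alone (median -0.07, adjusted p = 5.74e-11, and 0.0251 with an estimated correlation). VIM, the filament protein vimentin, fell by 0.54 ± 0.02 (SE) and 0.41 ± 0.02 (SE) and S100A4 by 0.56 and 0.44 in the authors' deposited tables. Epithelial markers rose, with 8 of 27 higher and 0 lower, or 10 adjusted over the list alone (median 0.31, adjusted p = 7.87e-14, and 0.0251 with an estimated correlation). KRT7 and KRT5, keratins, rose by 0.55 to 0.72 and ESRP1, an epithelial splicing factor, by 0.51 and 0.49 in the authors' deposited tables. Cholesterol synthesis rose, with 6 of 23 higher and 0 lower, or 7 adjusted over the list alone (median 0.35, adjusted p = 4.63e-10, and 0.0195 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, rose by 0.80 ± 0.09 (SE) and 0.80 ± 0.08 (SE), and FDPS and IDI1, enzymes of the isoprenoid steps, by 0.70 to 0.81 in the authors' deposited tables.

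The stress and unfolded protein response list fell with ITGAV guides in 4T1, with 5 of 24 lower and 0 higher, or 6 and 1 adjusted over the list alone (median -0.13, adjusted p = 3.49e-09, and 0.0252 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell by 0.48 ± 0.03 (SE) and 0.49 ± 0.03 (SE), and PDIA4, MANF and CALR, further proteins of that compartment, by 0.37 to 0.53 in the authors' deposited tables. MHC class I presentation fell, with 3 of 21 lower and 0 higher, also 3 adjusted over the list alone (median -0.14, adjusted p = 4.96e-09, and 0.0251 with an estimated correlation). Its 3 called members were the chaperones PDIA3, CALR and CANX, which serve many secreted proteins besides MHC class I, at -0.69 to -0.37 in the authors' deposited tables. Hypoxia and glycolysis had 3 of 27 higher and 0 lower, also 3 adjusted over the list alone (median 0.08, adjusted p = 0.000609, but adjusted p = 0.0702 with an estimated correlation). Among them were HK2 and GAPDH, glycolytic enzymes, at 0.22 to 0.57 in the authors' deposited tables. TGF-beta pathway and targets had 4 of 29 lower and 0 higher, or 5 adjusted over the list alone (adjusted p = 0.0390, but adjusted p = 0.163 with an estimated correlation). ID2, another inhibitor of the ID family, and LTBP2, a matrix protein, were at -0.81 to -0.61 in the authors' deposited tables. NF-kB targets had 1 of 17 lower, MMP9 (list median -0.12), and chemokines and cytokines 1 of 14 lower (list median -0.70), CSF1, the growth factor of macrophages at -0.59 and -0.75 in the authors' deposited tables, with the same counts adjusted over the list alone. These lists passed the preset test at adjusted p = 0.0159 and 0.0480, but with an estimated correlation at adjusted p = 0.0816 and 0.279. Fibroblast markers had 1 of 7 lower, also 1 adjusted over the list alone (median -0.58, adjusted p = 0.00132, with no estimated correlation because most members had too few reads). This was FBLN2, the matrix protein fibulin 2, at -0.51 and -0.64 in the authors' deposited tables. Cell cycle genes (adjusted p = 0.122), p53 targets (0.774), interferon receptors and checkpoint genes (0.880) and SOX factors (0.145) did not pass cameraPR. The LacZ and ITGAV libraries of 4T1 carried different run numbers, so run and edit coincide in these comparisons. The libraries of SOX4 gRNA2 came 1 from each run, and over the 401 genes called with ITGAV guides their difference had a slope of -0.0126 ± 0.0104 (SE) on the ITGAV change, where runs alone would give 1 in size. Limma called 1147 genes with both guides, and 752 without LacZ library a.

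With SOX4 guides in BT549 few genes passed with both guides. An adjusted p was deposited for 2835 of 15264 genes with gRNA1 and 4668 of 15455 with gRNA2, against 9433 and 11719 with the ITGAV guides. The lowest baseMean with an adjusted p was 1385 and 1022, so genes below these could not be called with both SOX4 guides. Few calls there do not show an absence of change. Counts adjusted over a list alone are free of this limit. The guides called 74 and 223 genes, and 47 passed with both in the same direction, 36 higher and 11 lower, against 2.72 for independent lists and 0 in simulated unchanged groups. By DESeq2, 0 called genes reached a log2 change of 1, while 655 and 1106 genes had an unadjusted p under 0.05 and limma called 566 and 885. Of the 13 mitochondrially encoded transcripts, 11 were higher with both guides and 0 lower, or 13 adjusted over the list alone (median 0.44, limma cameraPR adjusted p = 7.07e-254, and 0.0195 with an estimated correlation). The rise was as large with ITGAV guides against the same 2 LacZ libraries: the difference between the targets had a median of 0.01 (limma cameraPR adjusted p = 0.867), so it is not shown to be particular to SOX4. MT-ND4L, MT-ND1 and MT-ND5, subunits of respiratory complex I, rose by 0.66 to 0.72 with gRNA1 and by 0.35 to 0.50 with gRNA2, and MT-ATP8, of the ATP synthase, by 0.59 and 0.44 in the authors' deposited tables. MT-CO1 and MT-CO2 of complex IV, MT-CYB of complex III, and MT-ND2 and MT-ND4 rose by 0.48 to 0.61 with gRNA1 and by 0.28 to 0.31 with gRNA2 in the authors' deposited tables. PLEC, the linker protein plectin, rose by 0.34 ± 0.05 (SE) and 0.36 ± 0.04 (SE) in the authors' deposited tables. Falls were small: P4HA1, a collagen prolyl hydroxylase, GJA1, a gap junction protein, SERPINE2, a protease inhibitor, and COPS8, of the COP9 signalosome, lay between -0.26 and -0.19 in the authors' deposited tables. PLBD1, a phospholipase-like protein, SDCBP, the scaffold syntenin, and BNIP3L, a mitophagy receptor, lay between -0.22 and -0.17 in the authors' deposited tables. CTSB, a lysosomal protease, PDIA3, and SCD, a fatty acid desaturase, lay between -0.15 and -0.13 in the authors' deposited tables. COL3A1, a collagen chain, was the 1 gene called in opposite directions, at -0.20 and 0.13 in the authors' deposited tables.

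Interferon-stimulated genes as a list lay slightly lower with SOX4 guides in BT549, with 0 of 50 members called with both guides in DESeq2 and 0 adjusted over the list alone. At an unadjusted p under 0.05, 1 was higher and 3 lower with both guides, and limma called 3 lower (list median -0.06, limma cameraPR adjusted p = 2.67e-05, and 0.0251 with an estimated correlation). By DESeq2, gRNA1 alone had 1 member higher and 0 lower, and gRNA2 alone 0 higher and 9 lower, and the guides differed (median difference -0.08, limma cameraPR adjusted p = 2.19e-16). The list median by limma with gRNA1 was -0.0038 without LacZ library b and -0.03 without LacZ library a. With gRNA2 it was -0.12 and -0.10. PLSCR1, a phospholipid scramblase induced by interferon, was at -0.18 and -0.29 in the authors' deposited tables. Cell cycle genes passed the preset test upward (median 0.03, adjusted p = 0.0183, but adjusted p = 0.203 with an estimated correlation). The stress response (median -0.06, adjusted p = 0.0349, but adjusted p = 0.189 with an estimated correlation) and cGAS-STING list (median -0.12, adjusted p = 0.0496, but adjusted p = 0.203 with an estimated correlation) passed downward, each with 0 members called with both guides by DESeq2, also 0 adjusted over the list alone. At an unadjusted p under 0.05 these lists had 2 higher, 1 higher and 2 lower, and 1 lower with both guides, and limma called 1 in each. MHC class I presentation (adjusted p = 0.143), integrins (0.167), extracellular matrix (0.874), epithelial (0.685) and mesenchymal markers (0.643), cholesterol synthesis (0.994), hypoxia and glycolysis (0.676), TGF-beta pathway (0.875), NF-kB targets (0.594), p53 targets (0.159), chemokines (0.910), interferon receptors and checkpoint genes (0.0649), SOX factors (0.986) and fibroblast markers (0.874) did not pass. Limma called 293 genes with both guides, but 35 without gRNA1 library b, 87 without gRNA2 library a and 125 without gRNA2 library b. All 4 BT549 comparisons share the same 2 LacZ libraries, the pair with the highest mean chi-square, 2.60.

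ITGAV guides in BT549 raised the lists of mitochondrially encoded transcripts and hypoxia and glycolysis and lowered those of chemokines and cholesterol synthesis. Interferon-stimulated and cell cycle genes went opposite ways with the 2 guides. The mitochondrial rise was as large with SOX4 guides against the same LacZ pair, so it is not shown to be particular to ITGAV. The guides called 1128 and 2882 genes, and 594 passed with both in the same direction, 410 higher and 184 lower, against 163 for independent lists and at most 1 in simulated unchanged groups. A further 98 passed in opposite directions. MT-ND6 rose by 1.03 ± 0.10 (SE) and 0.72 ± 0.11 (SE) in the authors' deposited tables. PPFIA4, a liprin of synapses, rose by 0.59 and 1.99 and PLEC by 0.51 and 0.60 in the authors' deposited tables. PITX1, a homeobox factor of limb and pituitary, SMAD6, an inhibitor of BMP signals, CHTF18, of DNA replication, and the less known IGFN1, BAIAP2L2 and SBSPON rose by 0.50 to 1.23 in the authors' deposited tables. IL8, a neutrophil chemokine, fell by 0.70 ± 0.07 (SE) and 0.91 ± 0.08 (SE), and ENPP2, the enzyme autotaxin, by 0.77 and 1.08 in the authors' deposited tables. TNFSF15, a cytokine, ABCA1, a cholesterol exporter, NFE2L3, a transcription factor, GBP4, a guanylate-binding protein, CXCL6, a chemokine, PPP4R4, and CTSO, a protease, fell by 0.49 to 0.94 in the authors' deposited tables.

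Mitochondrially encoded transcripts rose in BT549 with ITGAV guides, with 11 of 13 higher and 0 lower, also 11 adjusted over the list alone (median 0.44, limma cameraPR adjusted p = 2.89e-69, and 0.0473 with an estimated correlation). The LacZ pair behind this and the SOX4 rise had the highest BT549 mean chi-square, 2.60. Hypoxia and glycolysis rose, with 9 of 27 higher and 0 lower, or 13 adjusted over the list alone (median 0.25, adjusted p = 1.89e-22, and 0.0396 with an estimated correlation). SLC2A1 rose by 0.48 and 0.91, and PFKL, PFKFB3 and TPI1, glycolytic enzymes, by 0.17 to 0.55 in the authors' deposited tables. Chemokines and cytokines fell, with 2 of 20 lower and 0 higher, or 3 adjusted over the list alone (median -0.39, adjusted p = 0.000349, and 0.0396 with an estimated correlation). CXCL1 and CXCL5, neutrophil chemokines, lay between -0.67 and -0.15 in the authors' deposited tables. Cholesterol synthesis fell, with 3 of 24 lower and 0 higher, or 6 and 1 adjusted over the list alone (median -0.14, adjusted p = 6.19e-06, and 0.0272 with an estimated correlation). INSIG1, STARD4, a sterol carrier, and FDPS lay between -0.57 and -0.16 in the authors' deposited tables. The stress response had 7 of 24 lower and 1 higher, or 10 and 1 adjusted over the list alone (median -0.17, adjusted p = 1.09e-05, but adjusted p = 0.0590 with an estimated correlation). SLC7A11, a cystine carrier, ASNS, asparagine synthetase, and HERPUD1 lay between -0.57 and -0.29, and SDF2L1, of the endoplasmic reticulum, at 0.31 and 0.29 in the authors' deposited tables.

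TGF-beta pathway and targets had 6 of 32 higher and 0 lower in the same comparison, or 7 adjusted over the list alone (median 0.12, adjusted p = 0.000130, but adjusted p = 0.0590 with an estimated correlation). TAGLN, a smooth muscle actin-binding protein, was at 0.49 and 0.56, LTBP3 at 0.36 and 0.35 and SKI, a repressor of SMAD factors, at 0.25 and 0.36 in the authors' deposited tables. Mesenchymal markers had 6 of 25 higher and 2 lower, or 7 and 2 adjusted over the list alone (median 0.11, adjusted p = 0.000142, but adjusted p = 0.210 with an estimated correlation). SNAI2, a transcription factor of epithelial-mesenchymal transition, and MYL9 and TPM1, contractile proteins, were at 0.27 to 0.57 in the authors' deposited tables. NF-kB targets had 2 of 19 lower and 1 higher, the same adjusted over the list alone (median -0.16, adjusted p = 0.000199, but adjusted p = 0.141 with an estimated correlation). SOD2, a mitochondrial superoxide dismutase, was at -0.46 and -0.34, ICAM1, an adhesion protein, at -0.28 and -0.50, and TNIP1, an NF-kB inhibitor, at 0.19 and 0.35 in the authors' deposited tables. Further lists passed the preset test and lost the call with an estimated correlation. These were p53 targets (1 of 22 lower, the cyclin gene CCNG1, or 2 adjusted over the list alone, median -0.14, adjusted p = 0.00345, and adjusted p = 0.0864 with an estimated correlation), extracellular matrix (1 of 40 higher and 1 lower, or 2 and 2 adjusted over the list alone, median 0.09, adjusted p = 0.0159, and adjusted p = 0.483 with an estimated correlation). Fibroblast markers were another (2 of 9 higher, also 2 adjusted over the list alone, median 0.16, adjusted p = 0.0348, and adjusted p = 0.557 with an estimated correlation). By DESeq2, interferon receptors and checkpoint genes had 0 of 18 called with both guides, 0 adjusted over the list alone, 3 lower at an unadjusted p under 0.05 and 4 lower by limma (median -0.13, adjusted p = 0.0438, and adjusted p = 0.167 with an estimated correlation). MHC class I presentation had 0 of 21 called, and 1 lower adjusted over the list alone, at an unadjusted p under 0.05 and by limma (median 0.13, adjusted p = 0.000480 upward, and adjusted p = 0.118 with an estimated correlation). Epithelial markers (2 of 26 higher, adjusted p = 0.646), SOX factors (1 of 11 higher, the transcription factor gene SOX12, adjusted p = 0.0766), cell cycle genes (0 of 35, adjusted p = 0.874) and integrins (2 of 18 lower, adjusted p = 0.994) did not pass. For integrins the median of 0.12 lay opposite to the mean of -0.07 and the test. Without ITGAV itself, 1 of 17 integrins was lower and the test pointed upward (median 0.13, cameraPR adjusted p = 0.414). Limma called 1825 genes with both guides, and 1041 without gRNA1 library b.

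The question whether the 2 guides of a target act alike was asked gene by gene. In BT549, 843 genes differed between the ITGAV guides, 444 higher and 399 lower with gRNA4. Interferon-stimulated genes led: gRNA1 lowered 39 of the 50 list members (median -0.46) and gRNA4 raised 35 and lowered 1 (median 0.45), by the deposited DESeq2 test. Their difference had a median of 0.96 (limma cameraPR adjusted p = 6.19e-240). IFI6, an inhibitor of cell death induced by interferon, was at -0.16 ± 0.05 (SE) with gRNA1 and 1.78 ± 0.05 (SE) with gRNA4, and OAS3, an RNA-sensing synthetase, at -0.32 ± 0.07 (SE) and 1.58 ± 0.06 (SE) in the authors' deposited tables. MX1, an antiviral GTPase, IFI44L and LY6E differed between the guides by 1.54 to 2.27 in log2. With both guides the list had 0 members called by DESeq2, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 1 lower by limma. The average of both guides had a median of -0.00187, a mean of 0.06 and an upward test (cameraPR adjusted p = 0.00345, but adjusted p = 0.370 with an estimated correlation), so median and test differed in sign. MHC class I presentation differed the same way (median difference 0.63, adjusted p = 6.45e-37), with HLA-B at -0.20 and 1.38 and HLA-C, a further presenting chain, at -0.12 and 0.83 in the authors' deposited tables. Mitochondrially encoded transcripts (0.33, adjusted p = 2.55e-19), hypoxia and glycolysis (0.21, adjusted p = 5.33e-12) and RIG-I and MDA5 sensing (0.02, adjusted p = 0.00334) were also higher with gRNA4 by limma cameraPR. Cell cycle genes (-0.23, adjusted p = 1.35e-12), cholesterol synthesis (-0.26, adjusted p = 3.23e-10) and fibroblast markers (-0.17, adjusted p = 0.00760) were lower. Integrins were higher with gRNA4 once ITGAV itself was left out (0.35, cameraPR adjusted p = 0.00583, against 0.0911 with it). List tests of differences, here and throughout, used no estimated correlation between genes, so their p-values may be too small. In list tests of single targets, 20 lost the threshold with an estimated correlation and 16 kept it. With gRNA4 lower than with gRNA1 were THBS1, CTGF and CYR61, secreted matrix-associated proteins, RCAN1, an inhibitor of calcineurin, and GFRA1, a receptor of glial growth factors, with differences of -0.96, -1.01, -0.75, -0.97 and -1.18. With gRNA1 of ITGAV in BT549, 2 called genes reached a log2 change of 1, MT-ND6 and RSPO3. The latter, an activator of Wnt signalling named after its value was seen, was at -1.08 in the authors' deposited table.

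**Figure D2:**
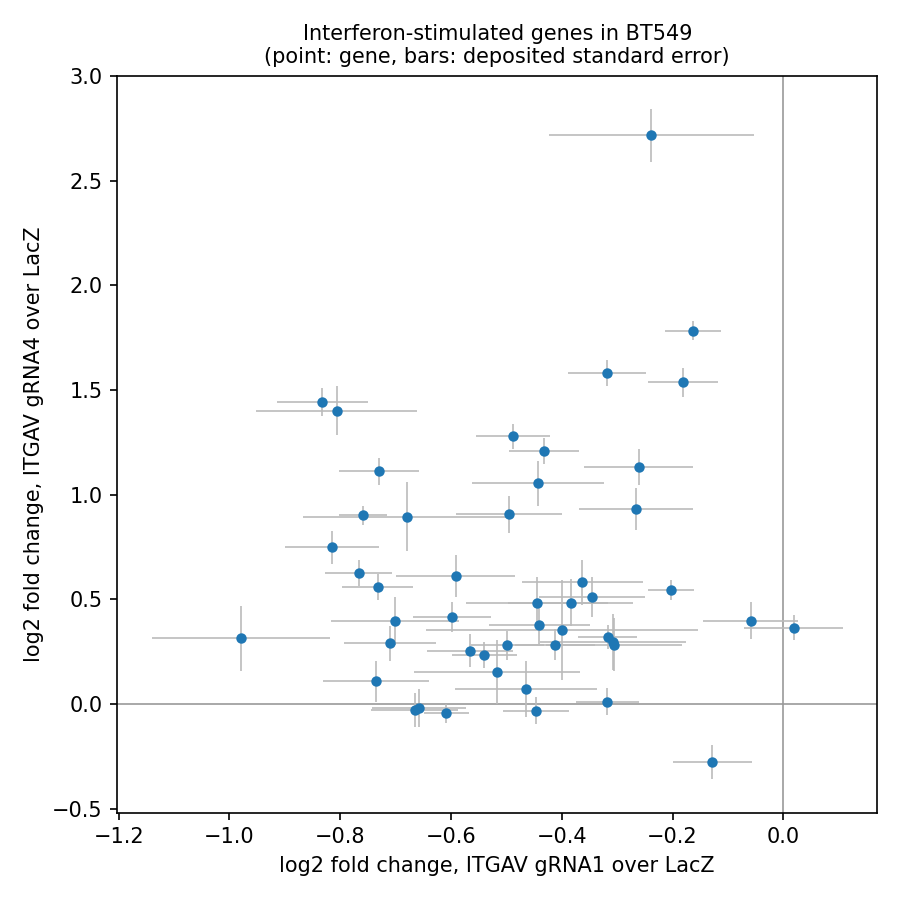
Log2 fold changes over LacZ of 48 interferon-stimulated genes in BT549 with a baseMean of at least 50, with ITGAV gRNA1 on the x axis and gRNA4 on the y axis; points are genes and bars are deposited standard errors. IFI6 sits at -0.16 and 1.78, and most points lie left of 0 and above 0.

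The other guide pairs differed in few single genes and in several lists. In BT549, 10 genes differed between the SOX4 guides. MT-ND1, MT-ND2, MT-ND4, MT-ATP6 and MT-CYB were lower with gRNA2 than with gRNA1, by -0.32 to -0.24 in log2, and COL3A1, COL1A1 and COL15A1, collagen chains, were higher with gRNA2 by 0.28 to 0.33. In 4T1, 4 genes differed between the SOX4 guides: THBS1, FN1, the matrix protein fibronectin, and MARCKSL1 were higher with gRNA2 by 0.42, 0.32 and 0.84, and for FOS the difference was -0.63. Between the ITGAV guides in 4T1, 12 genes differed, with MMP3 (1.33), FOS (0.92), NPTX1 (0.94), a secreted neuronal pentraxin, IGFBP4 (0.35), a binder of insulin-like growth factors, and LTBP3 (0.30) higher with gRNA4. Lower with gRNA4 were THBS1 (-0.39), PLK2 (-0.46), CYR61 (-0.32) and HSP90AA1 (-0.21). By limma cameraPR, lists lower with gRNA2 than with gRNA1 of SOX4 in BT549 were mitochondrially encoded transcripts (median difference -0.24, adjusted p = 2.28e-134), interferon-stimulated genes (-0.08, adjusted p = 2.19e-16), chemokines (-0.07, adjusted p = 0.00335) and NF-kB targets (-0.00922, adjusted p = 0.00681). Higher were extracellular matrix (0.08, adjusted p = 3.65e-25), fibroblast (0.04, adjusted p = 1.97e-17) and mesenchymal markers (0.08, adjusted p = 4.51e-12), TGF-beta pathway (0.04, adjusted p = 3.61e-06) and cholesterol synthesis (0.05, adjusted p = 4.99e-05). For SOX4 guides against LacZ in BT549, the estimated correlation was 0.512 for mitochondrial, 0.413 for fibroblast and 0.139 for extracellular matrix genes. No such correlation entered the tests of guides, so their p-values may be far too small. In 4T1, extracellular matrix (0.13, adjusted p = 6.90e-16), cholesterol synthesis (0.18, adjusted p = 1.06e-08), epithelial markers (0.17, adjusted p = 0.000582), fibroblast markers (0.42, adjusted p = 0.00696), the stress response (0.10, adjusted p = 0.0127) and integrins (0.11, adjusted p = 0.0395) were higher with gRNA2 than with gRNA1 of SOX4. Interferon receptors and checkpoint genes (-0.06, adjusted p = 0.0494) and mitochondrially encoded transcripts (-0.32, adjusted p = 0.0227) were lower. The mitochondrial list had a median baseMean of 5.77 there, with 3 of 7 members at 50 or above, and the fibroblast list 4.33, with 1 of 6, so both values rest largely on genes with few reads. Between the ITGAV guides in 4T1, integrins were higher (0.10, adjusted p = 0.000863, and 0.00104 without ITGAV itself) and fibroblast markers lower (-0.13, adjusted p = 0.0414) with gRNA4. Subtracting the covariance of the shared LacZ libraries gave 32, 28 and 36 genes, and 1995 for the ITGAV guides in BT549.

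SOX4 and ITGAV guides were compared to ask whether the edits change the same genes. In 4T1 the targets differed in 1478 genes, 790 higher and 688 lower with SOX4 than with ITGAV guides. FOS (mean log2 0.14 against -2.91), the chaperones HSPA5 (0.24 against -0.49) and HSP90B1 (0.29 against -0.56), and VIM (0.04 against -0.47) were higher with SOX4 guides. TMSB10, an actin-binding peptide (-0.99 against -0.03), MARCKSL1 (-1.83 against 0.14), TUBB, a tubulin (-0.31 against 0.20), ACTG1, an actin (-0.33 against 0.15), and HNRNPA0, an RNA-binding protein (-0.38 against 0.32), were lower. Called genes with opposite directions numbered 83 (higher with SOX4, lower with ITGAV guides; 12.4 for independent lists) and 16 (the reverse; 5.50). Those with the same direction numbered 11 higher (5.99 for independent lists) and 11 lower (11.3), with 0 in simulated unchanged groups. FDPS, HMGCS1, IDI1, INSIG1 and SCD, genes of lipid synthesis, were among the 11 raised by both. Across genes, which are not independent replicates, the 4 correlations between SOX4 and ITGAV fold changes in 4T1 ran from -0.13 to 0.06, against means of 0.459 to 0.539 in simulated unchanged groups. Their covariances ran from -0.00884 to 0.00354, against 0.0173 to 0.0174. The simulated noise came from the deposited standard errors, which imply more spread than the recovered replicates show, by the dispersions given above. The simulated covariances may therefore be too high. Within a target the correlation was 0.846 for SOX4 and 0.846 for ITGAV, against 0.444 and 0.558, with covariances of 0.0613 and 0.0472.

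The list tests of this difference in 4T1 put integrins (median difference 0.67, limma cameraPR adjusted p = 2.59e-17), MHC class I presentation (0.54, adjusted p = 1.17e-14), extracellular matrix (0.36, adjusted p = 1.74e-08), the stress response (0.23, adjusted p = 1.83e-05), cholesterol synthesis (0.22, adjusted p = 0.0121), TGF-beta pathway (0.08, adjusted p = 0.0227) and mesenchymal markers (0.01, adjusted p = 0.00335) higher with SOX4 than with ITGAV guides. Without ITGAV itself the integrins gave 0.64 (limma cameraPR adjusted p = 2.60e-11). These list tests, like those for BT549 below, used no estimated correlation between genes, so their p-values may be too small. In BT549 the targets differed in 548 genes, 237 higher and 311 lower with SOX4 guides. RCAN1 (-0.09 against -0.74), FASN, the fatty acid synthase (0.18 against -0.27), ABI3BP, a matrix protein (0.02 against -0.64), NUP210, a nuclear pore protein (0.26 against -0.44), and ITGAV (-0.08 against -0.67) were higher with SOX4 guides. IFI6 (-0.02 against 0.81), MGP, an inhibitor of calcification (-0.23 against 0.52), SPON2 (-0.04 against 0.44), TAGLN (-0.08 against 0.52) and TGFBI, a TGF-beta induced matrix protein (-0.14 against 0.30), were lower. For IFI6 the ITGAV mean hides opposite guides, at -0.16 with gRNA1, below the SOX4 mean, and 1.78 with gRNA4 in the authors' deposited tables. By limma cameraPR, lists lower with SOX4 than with ITGAV guides in BT549 were hypoxia and glycolysis (median difference -0.26, adjusted p = 2.06e-37), interferon-stimulated genes (-0.07, adjusted p = 1.10e-09), MHC class I presentation (-0.12, adjusted p = 5.44e-09), mesenchymal markers (-0.10, adjusted p = 3.99e-08), TGF-beta pathway (-0.09, adjusted p = 8.81e-07), extracellular matrix (-0.06, adjusted p = 0.000630) and SOX factors (-0.17, adjusted p = 0.0286). Without SOX4 itself the SOX factors did not pass (-0.13, cameraPR adjusted p = 0.149), and without ITGAV itself the integrins did (-0.21, cameraPR adjusted p = 0.0359, against 0.492 with it). The interferon and MHC class I values average ITGAV guides that went opposite ways. With ITGAV gRNA1 the interferon list had a median of -0.46, below the -0.06 of SOX4 guides, so these 2 lists are not shown to be lower than with each ITGAV guide. Fibroblast markers passed downward too (adjusted p = 0.00250), with a median of 0.12 of the other sign. Higher were cholesterol synthesis (0.15, adjusted p = 8.27e-10), chemokines (0.40, adjusted p = 5.45e-07), NF-kB targets (0.22, adjusted p = 1.83e-05), the stress response (0.09, adjusted p = 0.000114) and p53 targets (0.11, adjusted p = 0.00760). The targets shared 32 genes called higher (3.20 for independent lists) and 3 called lower, HSP90B1, PLBD1 and SCD (0.450), with 0 in opposite directions where independent lists would give 1.47 and 0.978. The shared LacZ libraries may account for part of this too. The 4 correlations between targets in BT549 ran from 0.351 to 0.695, against simulated means of 0.441 to 0.565, with covariances of 0.0106 to 0.0156 against 0.00967 to 0.00969. Within a target they were 0.710 for SOX4 and 0.442 for ITGAV, against 0.516 and 0.482, with covariances of 0.0105 and 0.0225 against 0.00967 and 0.00966. As in 4T1, the simulated covariances may be too high, so the excess over them may be understated. For BT549 SOX4 gRNA1 at a baseMean of 50 to 500, the deposited errors imply a dispersion of 0.0106, against 0.00130 between the recovered replicates.

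BT549 and 4T1 were compared to ask whether an edit has the same effect in both lines, by gene name. With ITGAV guides 638 genes differed, 416 higher and 222 lower in BT549. FOS (0.49 in BT549 against -2.91 in 4T1), FBLN2 (0.34 against -0.58), PLEC (0.55 against -0.21), VIM (0.10 against -0.47) and FLNA, an actin cross-linker (0.33 against -0.21), were higher. SCD (-0.45 against 0.65), FASN (-0.27 against 0.37), FDPS (-0.30 against 0.78), HMGCS1 (-0.15 against 0.80) and MYC, a growth regulator (0.02 against 0.70), were lower. With SOX4 guides 638 genes differed as well, 342 higher and 296 lower in BT549. TMSB10 (-0.02 against -0.99), MARCKSL1 (-0.04 against -1.83), DBN1 (0.05 against -1.51), TTYH3 (0.11 against -1.97) and PLK2 (0.00 against -0.89) were higher. SCD (-0.14 against 0.82), LTBP3 (0.11 against 0.71), PPIB, a folding enzyme (-0.07 against 0.46), HSP90B1 (-0.14 against 0.29) and CD9, a tetraspanin (0.05 against 0.66), were lower.

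The design text raises interferon-stimulated genes and the RIG-I/MDA-5, cGAS-STING and AIM2 pathways in edited 4T1 cells, a theme named there for these libraries, so it is not independent evidence. With SOX4 guides 32 of the 50 listed interferon-stimulated genes had a value, and 0 passed with both guides in DESeq2 or adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher with both guides, as by limma. Their median log2 was 0.60 and their mean 0.66, above 99.99% of random lists matched on baseMean, with a limma cameraPR adjusted p = 0.0752, and 0.189 with an estimated correlation. With ITGAV guides 31 had a value, 0 passed by DESeq2, by limma or at an unadjusted p under 0.05, also 0 adjusted over the list alone, and the median was 0.20 (cameraPR adjusted p = 0.874). The median baseMean of the list was 4.59 and 5.52, and 4 members reached 50, so most members had too few reads for small changes to be called. Whether sequencing depth or the matching of reads to human gene names left so few was not tested. LGALS3BP, a secreted lectin-binding protein, was at 0.67 ± 0.32 (SE) and 1.01 ± 0.29 (SE) with SOX4 guides, with DESeq2 adjusted p = 0.187 and 0.00710 in the authors' deposited tables. IFITM2, a membrane antiviral protein, was at 0.54 and 0.56, with DESeq2 adjusted p = 0.0961 and 0.0515 in the authors' deposited tables. IFIH1, which encodes the sensor MDA5, was at 1.37 ± 0.61 (SE) and 1.24 ± 0.59 (SE) with SOX4 guides and had no adjusted p in the authors' deposited tables. ENPP1, which breaks down cGAMP, was at 1.69 ± 0.55 (SE) and 1.60 ± 0.53 (SE), also with no adjusted p in the authors' deposited tables. It and DDX41, a DNA sensor at -0.34 and -0.31 in the authors' deposited tables, passed when adjusted over the cGAS-STING list alone, as they did by limma and at an unadjusted p under 0.05.

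By DESeq2, RIG-I and MDA5 sensing had 0 of 15 members called with either target in 4T1 (cameraPR adjusted p = 0.875 and 0.855) and 0 of 16 in BT549 (0.585 and 0.685), also 0 adjusted over the list alone. At an unadjusted p under 0.05 the list had 1 member higher with SOX4 guides and 1 lower with ITGAV guides in 4T1, as by limma, and 0 in BT549, where limma called 1 higher and 2 lower with ITGAV guides. The cGAS-STING list had 0 of 8 called in 4T1 (cameraPR adjusted p = 0.875 with SOX4 and 0.874 with ITGAV guides, the latter with 1 lower at an unadjusted p under 0.05 and by limma). In BT549 it had 0 of 10 with ITGAV guides (0.790), with 1 higher adjusted over the list alone and at an unadjusted p under 0.05, and 1 higher and 1 lower by limma. Here too the single ITGAV guides differed by DESeq2, with 0 higher and 3 lower for gRNA1 and 3 higher and 1 lower for gRNA4. AIM2 and NLRP3 inflammasome genes had 0 of 4 and 0 of 3 called in 4T1 (adjusted p = 0.997 and 0.774), with a median baseMean under 1, and 0 of 8 with SOX4 guides in BT549 (0.523), all also 0 by limma and at an unadjusted p under 0.05. With ITGAV guides there CASP4, an inflammatory caspase, was lower by both counts (1 of 8, adjusted p = 0.523), at -0.33 and -0.30 in the authors' deposited tables. Chemokines and cytokines (0 of 13), SOX factors (1 of 9 lower, SOX4 itself), fibroblast markers (0 of 6, or 1 higher adjusted over the list alone) and mitochondrially encoded transcripts (0 of 7) did not pass with SOX4 guides in 4T1, with cameraPR adjusted p = 0.874, 0.160, 0.536 and 0.922. Of these, fibroblast markers had 1 higher and 1 lower at an unadjusted p under 0.05 and by limma. Mitochondrially encoded transcripts with ITGAV guides in 4T1 had 1 of 9 lower, MT-CO1 at -0.61 and -0.46 in the authors' deposited tables, or 2 lower adjusted over the list alone, with a cameraPR adjusted p = 0.111. The limma fit kept 3 of these 9 members, with adjusted p = 0.0251 with an estimated correlation. The median of -0.34 and the mean of 0.50 differed in sign. Markers of other cell types had 0 members called with both guides in any comparison by DESeq2, also 0 by limma, at an unadjusted p under 0.05 or adjusted over the list alone: macrophage markers (adjusted p = 0.874 and 0.923 in 4T1, 0.684 and 0.874 in BT549), endothelial markers (no test with 2 measured members in 4T1, 0.742 and 0.938 in BT549) and lymphocyte markers (1 measured member in 4T1 and 2 in BT549, no test).

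**Figure D3:**
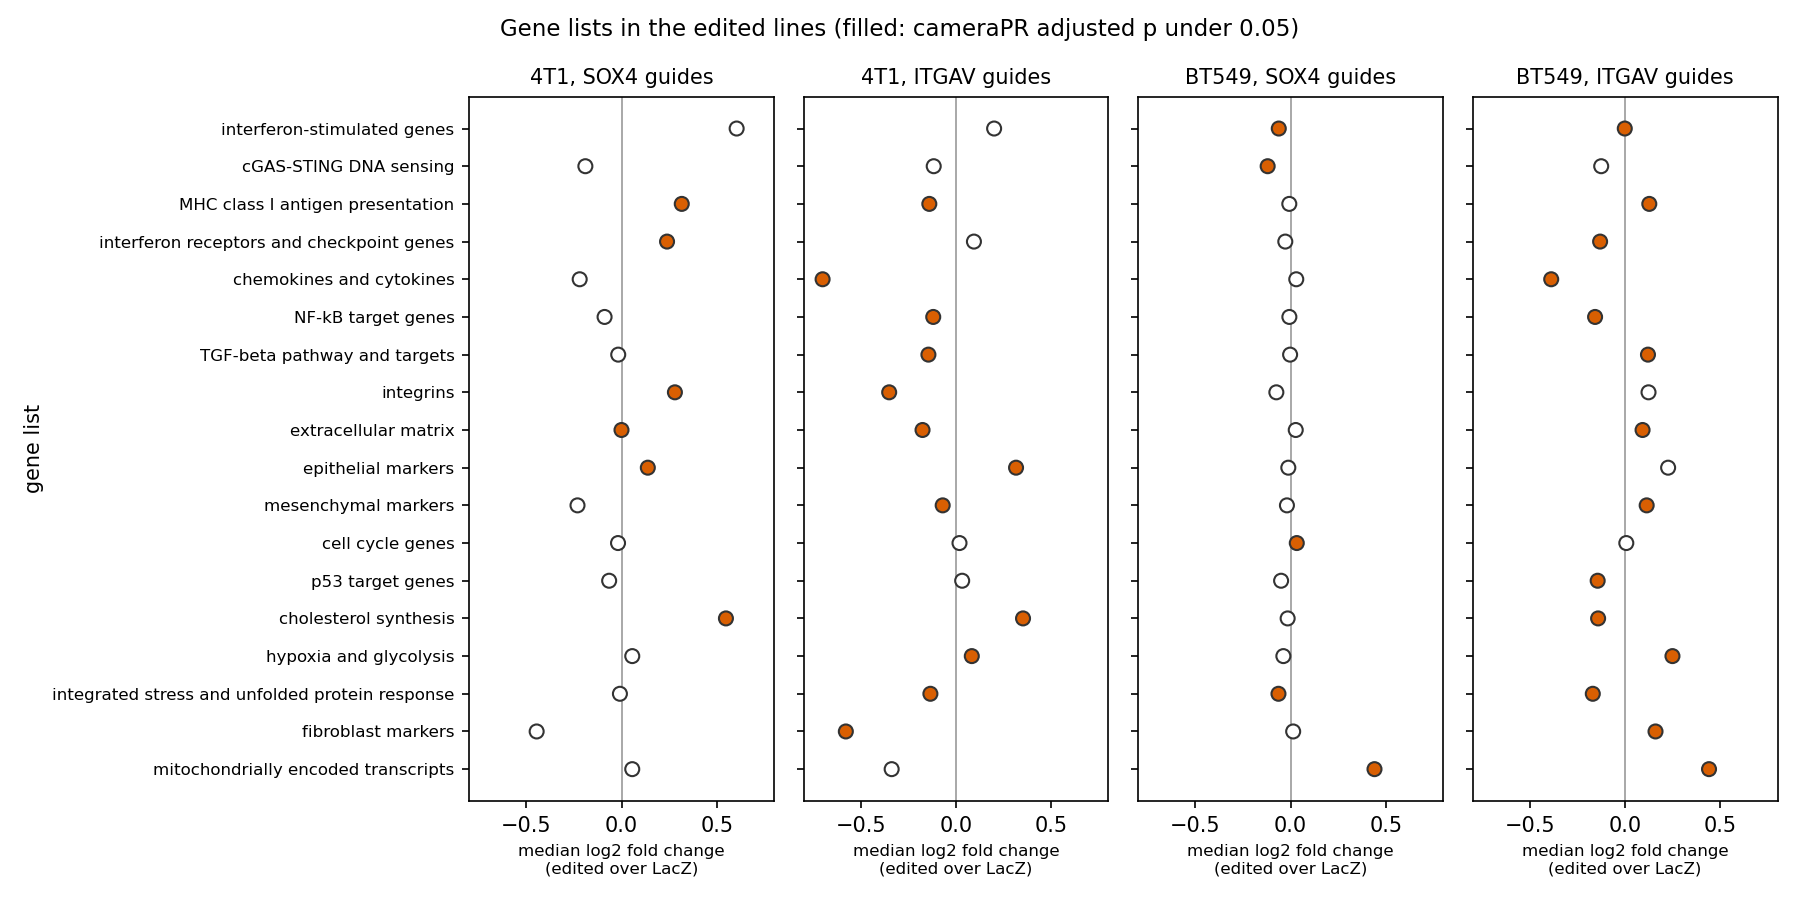
Median log2 fold change over LacZ, averaged over both guides, of each gene list that passed limma cameraPR in at least 1 comparison, in 4 panels for the 2 cell lines and 2 targets; filled points passed. Cholesterol synthesis sits at 0.55 and 0.35 in 4T1 with SOX4 and ITGAV guides and at -0.14 in BT549 with ITGAV guides.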

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

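Chosen only after the results were seen were the tests of a single library, of GC content and transcript length, and of converted gene names, and the list tests without the edited gene.

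Gene lists whose response to an edit differed between the cell lines, by limma cameraPR on the difference of fold changes over gene names listed for both, are given as the median difference in log2, BT549 minus 4T1. No estimated correlation between genes was used for these differences, so their p-values may be too small. With ITGAV guides, cholesterol synthesis differed by -0.40 (adjusted p = 1.01e-16, 23 genes). Higher in BT549 were extracellular matrix (0.31, adjusted p = 1.81e-07, 35 genes), fibroblast markers (0.92, adjusted p = 0.000157, 7 genes), integrins (0.50, adjusted p = 1.14e-06, 15 genes; 0.46 without ITGAV itself, adjusted p = 6.36e-05), mesenchymal markers (0.25, adjusted p = 7.49e-11, 21 genes) and MHC class I presentation (0.41, adjusted p = 2.90e-10, 21 genes). The last averages BT549 guides that moved opposite ways (difference between them 0.63), with a downward test with gRNA1 alone (adjusted p = 1.37e-07) and adjusted p = 0.118 in BT549 with an estimated correlation, so it is not shown for each guide. So were mitochondrially encoded transcripts (0.83, adjusted p = 0.000582, 9 genes), TGF-beta pathway and targets (0.45, adjusted p = 0.000534, 29 genes) and hypoxia and glycolysis (0.0638, adjusted p = 0.0154, 27 genes). The mitochondrial and fibroblast values rest largely on genes with few reads in 4T1, where 2 of 9 and 1 of 7 members reached a baseMean of 50 (median 2.45 for the mitochondrial list). With SOX4 guides, cholesterol synthesis (-0.62, adjusted p = 2.41e-25, 23 genes), integrins (-0.38, adjusted p = 0.000114, 14 genes), interferon receptors and checkpoint genes (-0.29, adjusted p = 0.00601, 10 genes) and MHC class I presentation (-0.33, adjusted p = 2.20e-09, 21 genes) were lower in BT549. The lines differ in species, depth and degree of transcript loss at once, so explanations of these differences cannot be told apart here, and none was tested.

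In BT549 the interferon-stimulated genes fell with ITGAV gRNA1 and rose with gRNA4. Library scaling was argued against by a median difference between the guides that stayed at 0.95 or above when libraries were scaled by totals or upper quartile. With each library left out the smaller list median stayed at 0.44 or more in size, which argues against 1 aberrant library. The list medians were -0.46 with gRNA1 and 0.45 with gRNA4, and ITGAV itself fell by 0.31 and 1.03 in the authors' deposited tables. The degree of ITGAV loss, a difference between the guides such as an effect away from ITGAV, or one between the cell populations made with them may be behind the opposite signs; these stay open, as no test here separates them and ITGAV protein was not measured.

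In 4T1, 99 genes passed in opposite directions with SOX4 and ITGAV guides. The libraries of SOX4 gRNA2 came 1 from each run, and their difference followed the ITGAV change over these genes with a slope of -0.08 (-0.0849 ± 0.0178, SE), where a run effect of the needed size would give at least 0.5. Shared LacZ libraries push the fold changes of both targets the same way, and were not tested as a source of opposite changes. Trends with GC content and length, fitted on the 6150 other genes, came to at most 0.09 and 0.10 for SOX4 and ITGAV, against median changes of 0.34 and 0.40 of these genes, and removing such trends left 96 of 96 with a transcript opposite, which argues against them as the whole cause; this test replaced a bound on the correlation (at most -0.1) that was not met (-0.0378 before and -0.0398 after correction). A hypothesis left standing is that the edits may act on these genes in opposite ways; other differences between the cell populations remain open.

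The 4T1 tables carry human gene names, with few reads of immune genes. Human RNA in the libraries would bring the abundant BT549 transcripts, but 18 of the 100 with the most BT549 reads held under 1% of their BT549 share. Conversion of names from a mouse count table, which the design text's homologue matching could imply, would leave MT-CO2 near MT-CO1, whereas it held 0.0239% of the MT-CO1 reads (7 of 29260; 50.5% in BT549), which argues against a plain renaming. That test replaced an earlier bound of at least 20 genes named after clones with 100 reads, not met with 6 of 57. Mouse reads counted on human gene models remain open and were not tested, and no biological explanation was tested.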

How the results depend on the processing

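Chosen after the data were seen were the limma fit, its runs with a library left out, with no filter and with 2 groups alone, camera on that fit, and lists without the edited gene. The comparison of edgeR's TMM with DESeq2 size factors, planned for tables with counts per sample, was not run. No paired analysis was possible because the recovered libraries carry no replicate number, so no replicate block was fitted. Low read counts limit lists such as the interferon list in 4T1, whose median baseMean with SOX4 guides was 4.59; whether more depth would raise them was not tested. Of the values of single lists under all alternatives, 241 kept direction and side of the threshold, 122 kept direction but lost the threshold and 4 reversed; for named genes 323 held, 8 lost it and 1 gained it. Except where stated, the cause was not tested for the values below.

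An adjusted p under 0.01 gave 456 and 491 genes for SOX4 gRNA1 and gRNA2 and 357 for ITGAV gRNA1 in 4T1, and 43, 108 and 707 for SOX4 gRNA1, gRNA2 and ITGAV gRNA1 in BT549. Both guides gave 317 for SOX4 in 4T1, and 25 for SOX4 and 331 for ITGAV in BT549. Overlaps of the targets became 6 higher, 5 lower, 48 higher with SOX4 and lower with ITGAV guides and 10 the reverse in 4T1, and 17 higher and 1 lower in BT549. With 0.1, SOX4 gRNA2 in BT549 had 377 genes and both guides 71. A minimum log2 change of 1 gave 46, 49, 11 and 8 genes for the 4T1 guides, 0, 0, 2 and 134 for the BT549 guides (in the order SOX4 gRNA1, gRNA2, ITGAV gRNA1, gRNA4), and 27 and 5 in 4T1 and 0 and 0 in BT549 with both guides of SOX4 and ITGAV. These lower counts follow from the stricter rule. Adjustment over every deposited p, which tests more genes, gave 139 for SOX4 gRNA2 in BT549 and 29 with both guides. A baseMean of at least 50 gave 30 there.

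Limma gave 2386, 2242, 1704 and 1849 genes for the 4T1 guides and 566, 885, 2996 and 5788 for the BT549 guides in the same order. With both guides it gave 1578 and 1147 in 4T1 and 293 and 1825 in BT549 for SOX4 and ITGAV. Every deposited call of the 8 guides (100%) was among them, and limma's standard errors were 0.580 to 0.768 of the deposited ones, so the larger counts reflect smaller errors. Without the filter on low counts limma gave 2011, 1849, 1393 and 1520 genes for the 4T1 guides, 357, 626, 2623 and 5519 for the BT549 guides, and 1267, 925, 181 and 1533 with both guides. With the 2 groups of a comparison alone it gave 2305, 2172, 1727 and 1978, then 310, 735, 2723 and 5186, and 1528, 1187, 165 and 1569. Limma differences gave 384 for the ITGAV and 369 for the SOX4 guides and 4922 for SOX4 against ITGAV in 4T1, and 4795, 134 and 4497 in BT549. With the shared covariance subtracted, which only shrinks the error, they gave 36, 28, 2589, 1995, 32 and 1597. For SOX4 itself with SOX4 gRNA1 in BT549, limma gave -0.23 with an adjusted p = 0.00560, past the threshold, against 0.0904. The combined statistic gave 927 and 671 genes in 4T1 and 120 and 1792 in BT549 for SOX4 and ITGAV, and at least 1 guide past the threshold 980, 743, 237 and 2644.

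With gRNA1 of each target alone, overlaps were 22 lower and 62 lower with SOX4 and higher with ITGAV guides in 4T1. In BT549 they were 13 lower, 1 higher with SOX4 and lower with ITGAV guides (OAS3) and 5 the reverse (COL1A1, COL3A1, CTGF, TAGLN and TGFBI), named after their values were seen. The 4 correlations between targets in 4T1 became -0.376, -0.237, -0.320 and -0.182 over genes with a baseMean of at least 500.

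Lists past the threshold fell with the log2 fold change as statistic to 3 for SOX4 and 4 for ITGAV in 4T1 and 3 for ITGAV in BT549. With an estimated correlation there were 3 for SOX4 in 4T1, 2 for SOX4 and 4 for ITGAV in BT549. A preset correlation of 0.05 left 2 for SOX4 in BT549, and 0.1 left 1 for SOX4 and 5 for ITGAV there. Ranks left 9 for ITGAV in BT549, and a baseMean of at least 50 left 3 for SOX4. Reversed were extracellular matrix with SOX4 guides in 4T1 with the log2 fold change (adjusted p = 0.832, downward), and with ITGAV guides in BT549 the interferon list with gRNA1 alone (1.08e-100, downward) and by random lists (percentile 43.6) and MHC class I presentation with gRNA1 alone (1.37e-07, downward). The last cases follow from the opposite signs of the guides.

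With each library left out in turn, the lone sample of its group is assumed to vary like the other groups. Limma then gave for both guides in 4T1 1094 to 1352 genes for SOX4 and 752 to 953 for ITGAV, and in BT549 35 to 319 for SOX4 and 1041 to 1824 for ITGAV. Single guides gave 1656 to 1905 and 1544 to 1866 for SOX4 gRNA1 and gRNA2 and 1160 to 1256 and 1111 to 1391 for ITGAV gRNA1 and gRNA4 in 4T1. In BT549 they gave 74 to 576, 160 to 760, 1686 to 2353 and 4163 to 5324. Counts moved over 1.5 times without LacZ library a for ITGAV in 4T1 (752 of 1147), without gRNA1 library b (35), gRNA2 library a (87) or gRNA2 library b (125 of 293) for SOX4 in BT549, and without gRNA1 library b for ITGAV in BT549 (1041 of 1825). For single guides they did so for ITGAV gRNA4 in 4T1 without its library b (1180) or LacZ library a (1111 of 1849), and in BT549 for SOX4 gRNA1 without its library b (74) or LacZ library b (341 of 566), for SOX4 gRNA2 without its library a (160), its library b (281) or LacZ library a (553 of 885), and for ITGAV gRNA1 without its library a (1976) or b (1686 of 2996).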

Other observations

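Gene Ontology terms were tested only after the results were seen. In 4T1 with SOX4 guides 187 of 1485 terms passed limma cameraPR, 99 higher and 88 lower. Beyond cholesterol synthesis, genes of RNA processing and protein synthesis were lower: mRNA splicing (155 genes, adjusted p = 1.06e-15), translational initiation (119 genes, adjusted p = 2.11e-11) and translational elongation (86 genes, adjusted p = 3.23e-08). Genes of the endoplasmic reticulum lumen (77 genes, adjusted p = 4.02e-11) and of TGF-beta binding (15 genes, adjusted p = 8.67e-10) were higher. With ITGAV guides 119 of 1481 terms passed, 22 higher and 97 lower. Lower were the smooth endoplasmic reticulum (20 genes, adjusted p = 1.10e-29), the melanosome (51 genes, adjusted p = 1.48e-29) and the endoplasmic reticulum lumen (78 genes, adjusted p = 2.96e-24), and microtubule-based process (35 genes, adjusted p = 1.94e-05) and adherens junction organization (16 genes, adjusted p = 0.00235) were higher.

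In BT549 with ITGAV guides 45 of 1683 terms passed cameraPR, 22 higher and 23 lower. Fatty acid synthesis (29 genes, adjusted p = 1.43e-05) and amino acid synthesis (16 genes, adjusted p = 0.00134) were lower, and structural constituents of muscle (26 genes, adjusted p = 2.70e-05), the podosome (19 genes, adjusted p = 0.000553) and the stress fiber (39 genes, adjusted p = 0.00299) were higher. With SOX4 guides 26 of 1679 terms passed, 17 higher and 9 lower. The respiratory electron transport chain (81 genes, adjusted p = 3.83e-27) was higher, and targeting of proteins to membranes by the signal recognition particle (92 genes, adjusted p = 0.00278) was lower. These terms overlap in their genes and rest on the preset correlation of 0.01.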
